A study of Mus musculus with 6 samples.

How the data were processed

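The series compared prostates of 4-week-old mice with an AR3 transgene (3 mice) and of wild-type littermates (3 mice). Per the labels' protocols, the authors extracted total RNA from dissected prostates with a column kit, treated it with DNase, and biotinylated the fragmented samples with a whole-transcript labelling kit for Affymetrix arrays. The deposited table held 1 value per probe set and array. These values are intensities on a linear scale, as read from the deposited values, which run from 0.87 to 21952, with a smallest value of 1 on 4 arrays. Summarisation, background correction, normalization and software are not given in the sources used here. Upper quantiles nearly coincided between arrays while medians did not, so the values were taken as already normalized between arrays and were not normalized again, except in the alternatives named below.

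The table held 35512 probe sets. Of these, 6568 with identifiers below the gene-level range of this array type were taken for controls, from knowledge of the platform, and left out, leaving 28944. Among the 6568, limma called 0 at an adjusted p of 0.05, while 545 (8.30%) had an unadjusted p under 0.05, and their median log2 change was −0.08 against 0.01 for the tested probe sets. Gene symbols came from the platform annotation given with the data: 21789 tested probe sets had 1 symbol, 1621 had several and 5534 have no symbol here. Symbols were matched to the RefSeq gene table of assembly GRCm38.p6, which held 21698 of the 21789, and that table was used for names and for which genes neighbour each other. No gene was named from a probe set with several symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays stood for the gene, which gave 19938 genes. Of the called genes, 15 had several probe sets; in 5 another probe set had the opposite sign, and in 8 another was also called.

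Intensities were tested as log2(intensity + 16) with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 3 transgenic against 3 wild-type arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over all 28944 probe sets and a threshold of 0.05. The added constant of 16 understates changes of dim genes. Every adjusted p given for a gene is from this limma fit unless another setting is named, and each change is transgenic minus wild-type with its standard error. Means and SDs are of the deposited intensities. With 3 against 3 arrays an exact permutation test of a single gene cannot go below 0.1 two-sided, so none was used. No scan date or array batch was used here, so none could be tested.

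Before the data were examined, 36 gene lists were written down from general knowledge of the prostate, of the transgene and of other cell types that a dissected prostate can hold. Of their 919 symbols, 828 were measured. They cover androgen-responsive and secretory genes, luminal and basal epithelium, progenitors, growth factors, TGF-β and epithelial-mesenchymal transition, extracellular matrix, cell cycle, prostate development, steroid metabolism, polyamine, citrate and zinc, the unfolded protein response, lipid synthesis, interferon, inflammation, Wnt targets, Akt and MAPK signalling, seminal vesicle, vas deferens and epididymis, urothelium, skeletal and smooth muscle, fibroblasts, adipocytes, endothelium, myeloid, T and NK, B and mast cells, nerve and glia, neuroendocrine cells, erythrocytes, immediate early genes, histones, oxidative phosphorylation and ribosomal proteins. Some genes stand on several lists. Each list was tested against all other genes with camera and a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Of the 36, 9 were called, 8 higher and 1 lower. With an estimated correlation camera called 0 lists (smallest adjusted p 0.54), and 3 had an unadjusted p under 0.05. On ranks, camera called 10. The fry test, which asks whether a list's genes move on balance one way, called 10. Of the 9 lists that camera called, fry called the progenitor, Akt and myeloid lists (adjusted p 0.034, 0.034 and 0.041). Not called by fry were the basal (0.30), TGF-β (0.062), extracellular matrix (0.26), unfolded protein response (0.090), interferon (0.090) and fibroblast (0.32) lists. The mixed version of fry, which asks whether genes change in either direction, called 20.

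The genes named were set by a rule fixed at the same time: the 12 largest rises and 12 largest falls by log2 change among genes past the threshold whose genotypes do not overlap, skipping predicted, olfactory and small RNA genes (0 skipped among rises, 1 among falls), up to 4 members of each list with the smallest p, and Igf1, Tgfb2 and Pbsn whatever their values. Some genes fixed by that rule are not reported here. Genes named outside that rule are said to be singled out afterwards. The alternatives tried were quantile normalization, median centring, leaving out the dimmest 40% of probe sets, an intensity trend with robust variances, array weights, the mouse number as a replicate block, the mean of a gene's probe sets, added constants of 1 and 64, 1 probe set per gene, each array left out in turn, thresholds of 0.1 and 0.01, a minimum log2 change of 1, and a test against a 1.2-fold change. The level of Svs2, Svs4 and Svs5 as a covariate was added after the data were seen.

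The fit was tested on simulated data for the same 28944 probe sets with 200 changed probe sets, 50 at each size. It called 26% of changes of 0.5 on the log2 scale, 90% of changes of 1, 96% of changes of 2 and 100% of changes of 3, with 7 false calls among 163. A gene list lowered by design was the only list called, and data simulated without any change gave 0 called probe sets and 0 called lists. Simulated probe sets were drawn independently of each other. In the real data the estimated correlation was 0.48 for the extracellular matrix list and reached 0.71 for the smooth muscle list. The simulation therefore cannot show how often the list test errs on correlated genes. Figures were drawn with matplotlib 3.10.9.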

Results

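Gene expression was measured in whole prostates of 4-week-old mice, 3 carrying an AR3 transgene and 3 wild-type littermates, with 1 array per mouse. The labels name every sample as a separate mouse, so the limma p-values below rest on the spread between mice. The p-values of camera with a preset correlation, of the gene family test and of the neighbouring gene permutations take genes as the units. Those do not measure the spread between mice. The array summarised 28944 probe sets other than controls, and 19938 genes could be followed through a probe set with 1 gene symbol. Median intensity per array lay between 94.5 and 110.8. No detection calls were used, so 1035 probe sets of olfactory receptor genes served as a scale of background. Their 95th percentile of intensity lay between 66.9 and 91.9 on the 6 arrays. Genes below were set against the lowest of these, 66.9, so genes with means up to 91.9 can lie at background on some arrays. The number of arrays, 3 per genotype, limits the precision of every value. The first principal component held 45.1% of the variance and separated the genotypes. The second held 25.8% and separated wild-type replicate 1, at 30.8, from wild-type replicate 3, at −22.3.

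The series asked which genes differ in expression between AR3 transgenic and wild-type prostates at 4 weeks. Of 22 measured genes of the kallikrein proteases 8 were called, all higher in transgenic prostates, among them Klk1b24 and Klk1b27, and the other 14 did not pass the threshold. The prohormone convertase Pcsk1, the secreted siderophore-binding protein Lcn2, the amylase Amy1 and the secretory gene Ceacam10 also rose. The secretoglobin Scgb2b27 fell furthest, and the mucosal immunoglobulin transporter Pigr, the retinoic acid binding protein Crabp1 and the neuropeptide precursor Tac1 fell as well. Of 36 measured androgen-responsive and secretory genes, 3 were higher and 6 lower. Of the 3 higher genes, Ceacam10 is also on the seminal vesicle list and Adam7 on the vas deferens and epididymis list. The wild-type means of both lay below the background scale (42.3 and 17.1). By camera with a preset correlation, myeloid and progenitor marker lists lay higher in transgenic prostates. The genes of protein folding in the endoplasmic reticulum lay lower by the same test. None of these list calls held with an estimated correlation, and fry did not call the protein folding list (adjusted p 0.090).

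At an adjusted p of 0.05 (limma), 425 of 28944 probe sets differed between the genotypes, of which 305 were higher and 120 lower in transgenic prostates. After median centring of the arrays, a choice that moved the balance, 314 were higher and 264 lower. Counted by gene, 324 of 19938 differed, 234 higher and 90 lower. Among them, 128 had a log2 change of at least 1 in either direction, 99 higher and 29 lower. A log2 change of at least 2 was seen for 31 higher and 4 lower genes. In all 324 genes the 3 transgenic values lay outside the range of the 3 wild-type values, a separation that 19.1% of all genes showed and that chance gives for 10%. The call count moved by over 1.5 times to 254, 248 and 234 probe sets without wild-type replicate 2, transgenic replicate 2 or transgenic replicate 3. It moved as far to 250 with the mouse number as a replicate block, to 678 with an intensity trend and robust variances, and to 1202 with array weights.

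**Figure D1:**
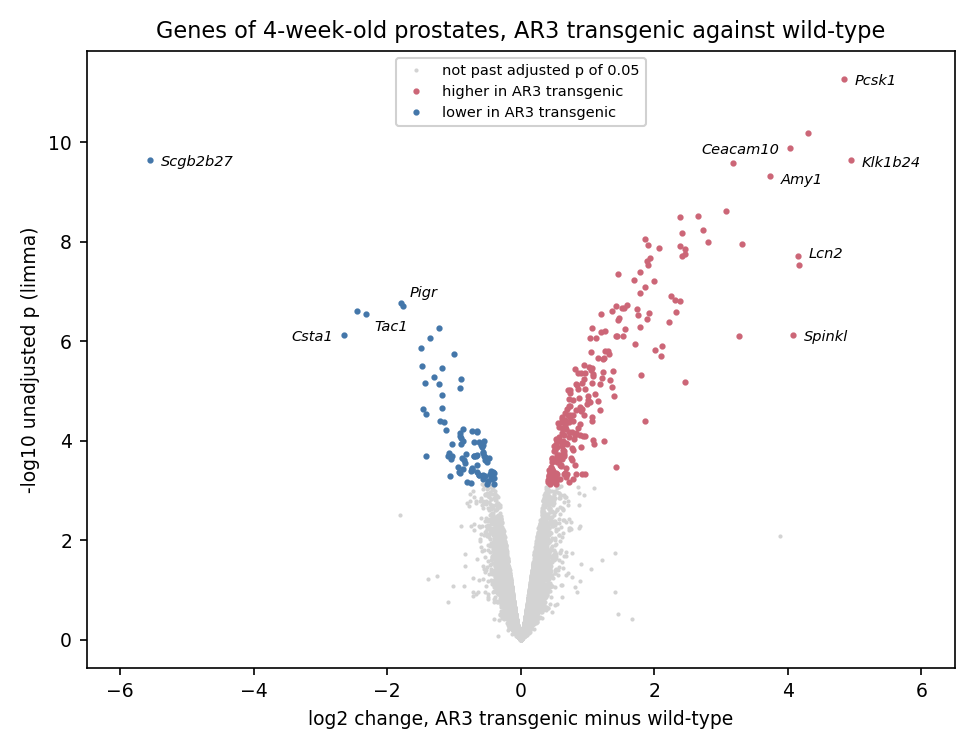
Log2 change (AR3 transgenic minus wild-type, x axis) against −log10 of the unadjusted limma p (y axis) for 19938 genes, with coloured points for genes past an adjusted p of 0.05. The 234 higher genes reach further from 0 than the 90 lower genes, apart from Scgb2b27 at −5.55.

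Which genes rose most depends on the added constant: with 16, used here, Klk1b24 and Pcsk1 led, with 1 Pcsk1 (5.55) lay above Klk1b24 (5.29), and with 64 Lcn2 (3.83) lay above Pcsk1 (3.72). Without wild-type replicate 1 and with array weights, Pate4 was called and lay above all of these (5.33 and 5.04). Klk1b24 went from an intensity of 54.8 ± 10.6 (SD, n = 3) in wild-type to 2162 ± 111 (SD, n = 3) in transgenic prostates, a log2 change of 4.95 ± 0.12 (SE) with an adjusted p of 8.7e-07. Pcsk1, which cleaves prohormones, went from 21.7 ± 0.59 to 1061 ± 20.3, with a log2 change of 4.84 ± 0.07 and an adjusted p of 7.7e-08. Klk1b27 rose by 4.31 on the log2 scale and Klk1b7-ps, a kallikrein pseudogene, by 3.27. The Kazal-type protease inhibitor genes Spink11 and Spinkl rose by 4.17 and 4.08, and Spinkl varied most between transgenic mice (672.5 ± 218). Lcn2 rose from 175.3 ± 46.4 to 3303 ± 18.3, a log2 change of 4.15 ± 0.17 with an adjusted p of 1.7e-05. Amy1 rose from 131.7 ± 11.3 to 1953 ± 159, a log2 change of 3.74 ± 0.10 with an adjusted p of 8.7e-07. The rises of Ceacam10 (4.03), the acid nuclease Dnase2b (3.31), the sulfotransferase Sult1b1 (3.17) and the protease inhibitor Mug1 (3.07) complete the 12 largest. For 10 of these 12 genes, all but Lcn2 and Amy1, the wild-type mean lay below the background scale of 66.9, so their log2 changes depend on the added constant of 16. Probe sequences were not used here, so signal shared among the near-identical kallikrein genes was not separated.

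Scgb2b27 fell from 2321 ± 303 (SD, n = 3) in wild-type to 33.8 ± 6.34 (SD, n = 3) in transgenic prostates, a log2 change of −5.55 ± 0.13 (SE) with an adjusted p of 8.7e-07. The cysteine protease inhibitor Csta1 went from 218.7 ± 60.2 to 20.6 ± 1.70, a log2 change of −2.65, and Tac1 from 151.8 ± 26.5 to 17.6 ± 4.24, a log2 change of −2.32. Pigr fell from 1770 ± 200 to 497.5 ± 22.6, with a log2 change of −1.79 ± 0.10 and an adjusted p of 9.8e-05. Crabp1 fell from 671.2 ± 84.2 to 185.5 ± 6.33, with a log2 change of −1.76 ± 0.10 and an adjusted p of 1.1e-04. Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, had a log2 change of −1.36. The other 6 of the 12 largest falls were the prostaglandin receptor Ptgdr (−1.49), Caln1 (−1.48), the metalloproteinase inhibitor Timp4 (−1.46), the lipid kinase Pik3c2g (−1.44), the seminal vesicle secretory gene Svs3a (−1.43) and the monocarboxylate transporter Slc5a8 (−1.42). The call on Svs3a (adjusted p 0.019) was lost without wild-type replicate 2, transgenic replicate 1 or transgenic replicate 3, where its adjusted p reached 0.107. In 4 of the 12, namely Scgb2b27, Csta1, Tac1 and Caln1, the transgenic mean lay below 66.9 on the background scale. The transgenic means of Ptgdr (82.0) and Pik3c2g (86.3) lay within its range over the arrays, 66.9 to 91.9. With an added constant of 64 the log2 changes of Csta1, Tac1 and Caln1 were −1.72, −1.40 and −0.91. That of Scgb2b27 ran from −6.07 to −4.60 over all settings.

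**Figure D2:**
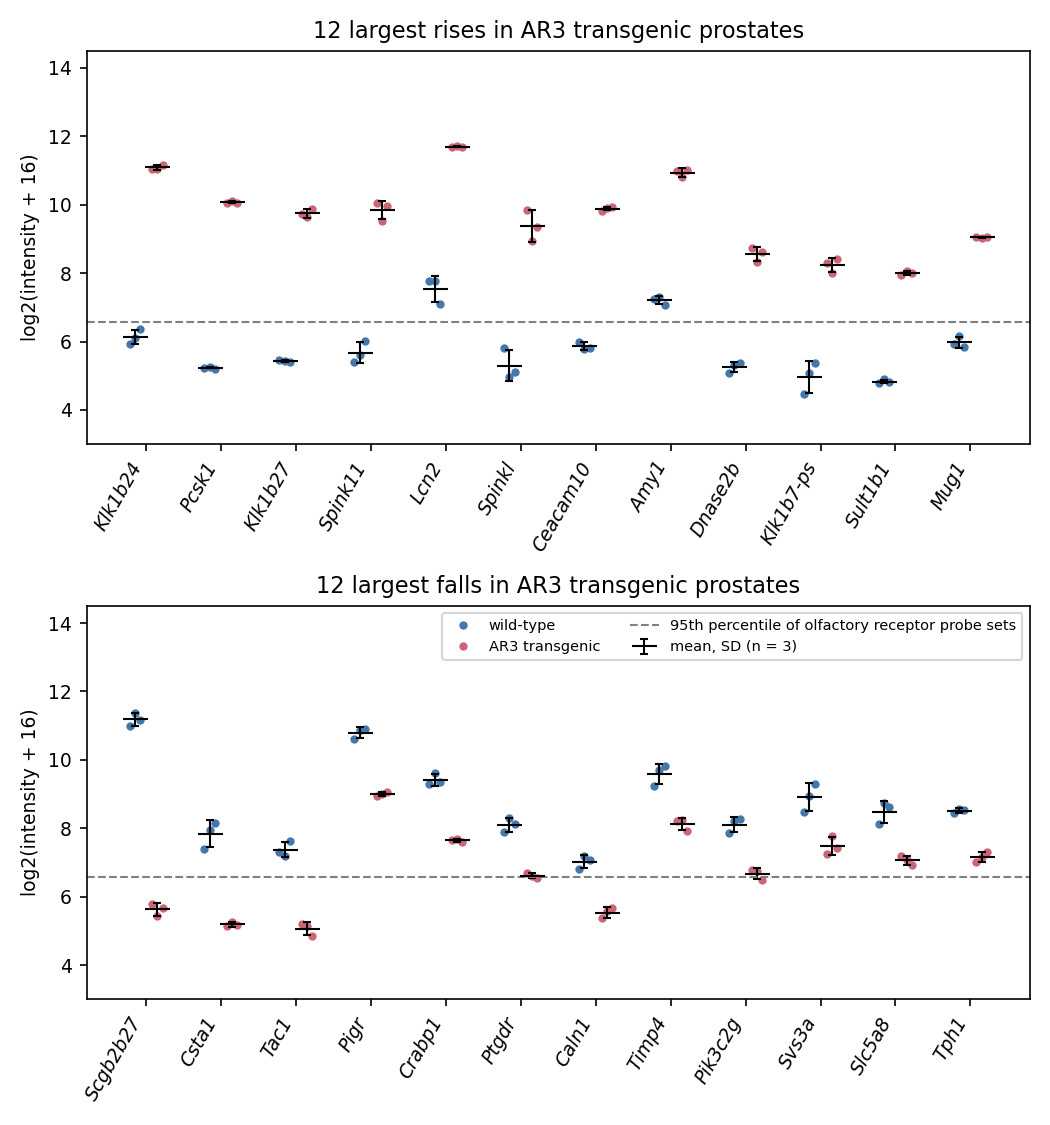
Log2(intensity + 16) of the 12 largest rises (top) and 12 largest falls (bottom) in each of the 3 wild-type and 3 AR3 transgenic mice (points), with the mean and SD as bars and the mean 95th percentile of olfactory receptor probe sets as a dashed line. In each gene the genotypes do not overlap, and 10 of the 12 rises start below the dashed line.

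Of 36 measured androgen-responsive and secretory genes of the prostate, 3 were higher, 6 lower and 27 not past the threshold over all genes tested; adjusted over the list alone, 6 were higher and 12 lower. The higher members were Ceacam10, the metalloprotease-family gene Adam7 (2.41 ± 0.09, adjusted p 8.6e-06, with a wild-type mean of 17.1, below the background scale of 66.9, and log2 changes of 3.16 and 1.46 with added constants of 1 and 64) and the metalloreductase Steap4 (1.09). The lower members were Pigr, Crabp1, Azgp1 (−1.17), the apolipoprotein Apof (−1.08), the secretory spermine-binding protein gene Sbp (−0.91) and the protease inhibitor Spink1 (−0.53). Sbp stayed among the brightest genes, at 7752 ± 658 in wild-type and 4107 ± 142 in transgenic prostates. Pbsn, the androgen-driven secretory gene probasin, was at 9343 ± 366 and 8078 ± 216, with a log2 change of −0.21 ± 0.07 and an adjusted p of 0.31, against 0.012 with an intensity trend and robust variances. The transglutaminase Tgm4, a product of the anterior lobe singled out after its values were seen, as were Sbp, Azgp1, Apof, Spink1 and Steap4, had a log2 change of 0.07 ± 0.07 and an adjusted p of 0.77. As a whole the list was not called (camera, adjusted p 0.15), although without the dimmest probe sets it was called lower (0.0094), and its mean and median changes of 0.03 and 0.01 had the opposite sign to camera's direction, which was down. Without single arrays the calls on Apof (wild-type replicate 2, transgenic replicates 2 and 3), Spink1 (wild-type replicate 2, any transgenic replicate) and Steap4 (any transgenic replicate) were lost, with adjusted p up to 0.104, 0.122 and 0.077.

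The seminal vesicle list held 16 measured genes, of which 2 were higher (Ceacam10 and Spinkl), 2 lower (Svs3a and 9530002B09Rik) and 12 not past the threshold; adjusted over the list alone, 4 were higher and 2 lower. The change of 9530002B09Rik, −0.51 with an adjusted p of 0.0496, was lost without any 1 array other than wild-type replicate 1, at up to 0.243. The abundant seminal vesicle genes Svs2, Svs4 and Svs5, singled out after their values were seen, differed between mice of 1 genotype. Their mean log2 intensity was 10.05, 5.36 and 5.42 in wild-type replicates 1, 2 and 3, and 7.53, 5.53 and 10.54 in transgenic replicates 1, 2 and 3. Pate4, also singled out afterwards, had a log2 change of 3.88 ± 1.09 with an adjusted p of 0.20, and of 5.33 with an adjusted p of 6.1e-04 without wild-type replicate 1. Camera did not call the list (adjusted p 0.23), except without wild-type replicate 1, where it was called higher (0.0252). Among 15 measured vas deferens and epididymis genes, Adam7 and the protease inhibitor family gene Wfdc8 (0.82 ± 0.09, adjusted p 0.0038) were higher, both from wild-type means below the background scale of 66.9 (39.6 for Wfdc8, whose log2 change was 0.50 with an added constant of 64), none was lower, and the 2 were also those past the threshold adjusted over the list alone (camera, adjusted p 0.41).

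**Figure D3:**
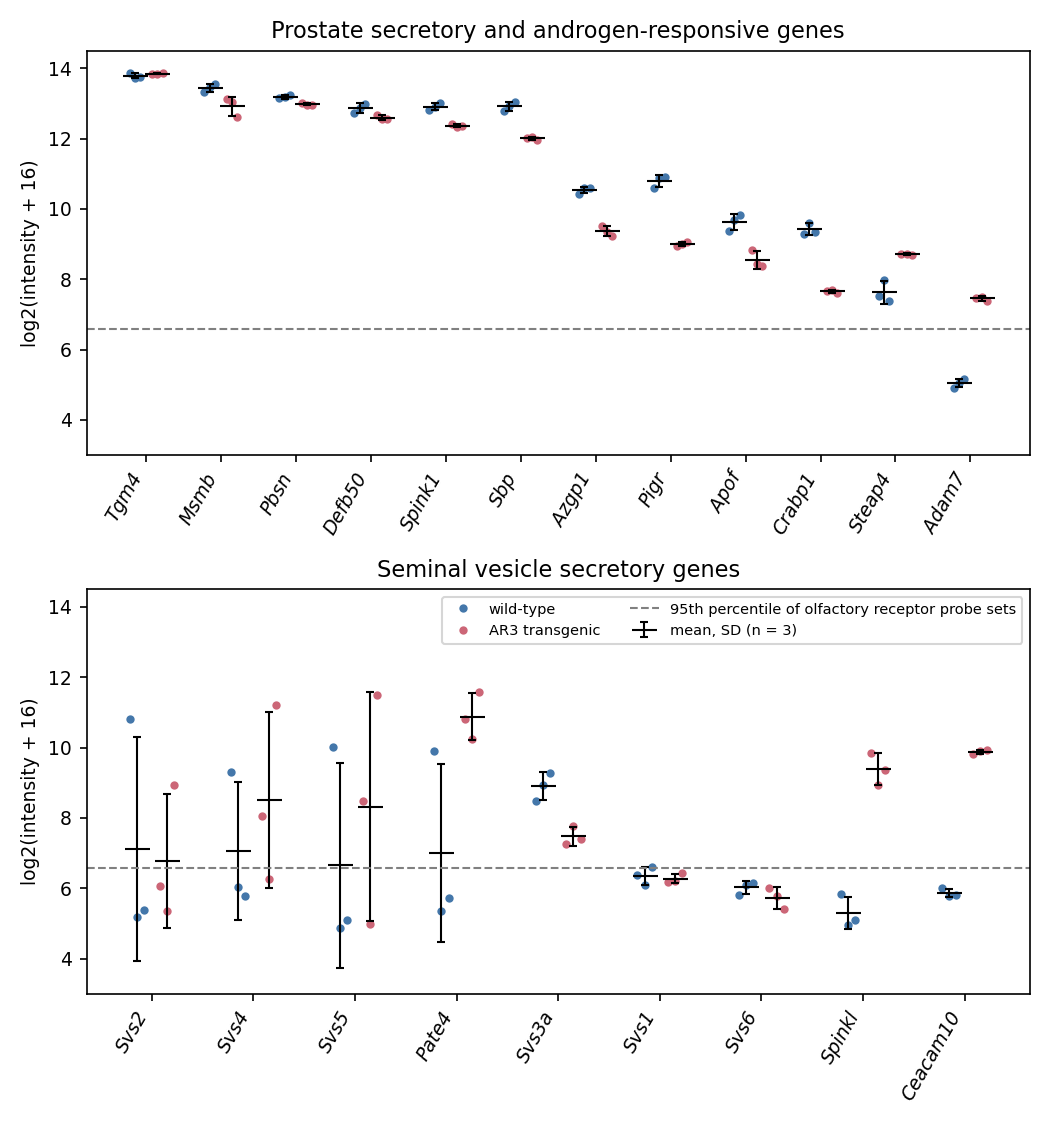
Log2(intensity + 16) of 12 prostate secretory genes (top) and 9 seminal vesicle genes (bottom) in each mouse (points), with the mean and SD as bars and the mean 95th percentile of olfactory receptor probe sets as a dashed line. Svs2, Svs4, Svs5 and Pate4 vary between mice of 1 genotype, while Spinkl and Ceacam10 separate the genotypes.

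Epithelial markers showed few calls. Of 23 luminal markers, the keratin Krt7 (1.06 ± 0.09, adjusted p 9.2e-04) and the peptidase Dpp4 (0.65, adjusted p 0.019) were higher, none was lower, and adjusted over the list alone 3 were higher and 1 lower; camera did not call the list (adjusted p 0.25). Of 24 basal markers, the desmosome-associated gene Perp (0.48, adjusted p 0.044) was higher, also adjusted over the list alone. Camera called the basal list higher, with a median log2 change of 0.10 and an adjusted p of 0.048, against an adjusted p of 0.68 with an estimated correlation. That call was lost without wild-type replicate 1 (0.263), wild-type replicate 3 (0.0945), transgenic replicate 2 (0.0963) or transgenic replicate 3 (0.151), and in 10 of 19 settings in all. The call on Perp was lost without any 1 of the 6 arrays, with an adjusted p between 0.068 and 0.230, and that on Dpp4 without any array but wild-type replicate 1, at up to 0.118.

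Of 25 progenitor and stem cell markers, 3 were higher and none lower: Ly6e (0.71 ± 0.07, adjusted p 0.0018), the retinaldehyde dehydrogenase Aldh1a1 (0.99 ± 0.11, adjusted p 0.0032) and the prostate stem cell antigen Psca (0.97 ± 0.13, adjusted p 0.0097). Adjusted over the list alone, 6 were higher and 1 lower. The list had a median log2 change of 0.19 and an adjusted p of 0.0014 by camera, against an adjusted p of 0.54 with an estimated correlation. Aldh1a1 was bright in both genotypes, at 1943 ± 248 and 3848 ± 114. Psca was not called without transgenic replicate 1 or 2, at up to 0.064.

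Among 44 measured growth factor genes, only Hgf, the ligand of the Met receptor, passed the threshold, from 56.0 ± 3.95 to 95.2 ± 7.47 with a log2 change of 0.63 ± 0.09 and an adjusted p of 0.011; it was also the sole call adjusted over the list alone. The wild-type mean of Hgf lay below the background scale of 66.9, and its log2 change was 0.41 with an added constant of 64. Hgf lost its call without wild-type replicate 2, transgenic replicate 2 or transgenic replicate 3, at up to 0.070. Igf1 had a log2 change of 0.63 ± 0.23 and an adjusted p of 0.33 (0.047 with array weights), and Tgfb2 of 0.18 ± 0.08 and 0.43. The growth factor list was not called (camera, adjusted p 0.25). Of 26 Akt, MAPK and tumour suppressor genes, the cyclin Ccnd2 (0.70, adjusted p 0.035) and the IGF-binding protein Igfbp5 (0.72, adjusted p 0.047) were higher and none lower; adjusted over the list alone, 6 were higher. Camera gave this list an adjusted p of 0.0036 with a median change of 0.10, against an adjusted p of 0.54 with an estimated correlation. Ccnd2 and Igfbp5 were not called without any 1 array other than wild-type replicate 1, at up to 0.165 and 0.218.

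No gene of the TGF-β and epithelial-mesenchymal transition list (28 measured) or the extracellular matrix list (29 measured) passed the threshold in limma; 4 and 9 members had an unadjusted p under 0.05, all with positive changes, and adjusted over the list alone 1 and 0 were higher. Twist2, a mesenchymal transcription factor, had a log2 change of 0.33 ± 0.07 and an adjusted p of 0.083 (0.030 without the dimmest probe sets and 0.029 with array weights), and the collagen Col1a1 of 0.45 ± 0.17 and 0.34. Camera called both lists higher, with median changes of 0.15 (adjusted p 0.0020) and 0.29 (adjusted p 2.2e-05). With an estimated correlation the adjusted p was 0.57 for each. Of 19 fibroblast genes, the selenoprotein Gpx3 was lower (−0.57, adjusted p 0.014), none was higher, and adjusted over the list alone the count was the same 1 lower gene. Camera called the fibroblast list higher (median 0.32, adjusted p 0.0025, against an adjusted p of 0.57 with an estimated correlation), while its sole called gene was lower. The mean log2 level of the fibroblast list was 8.02, 7.54 and 7.51 in wild-type replicates 1, 2 and 3, and 7.90, 7.91 and 8.25 in transgenic replicates 1, 2 and 3. The extracellular matrix list lay at 8.05, 7.85 and 7.74 and at 7.97, 8.09 and 8.38 on the same arrays. Without wild-type replicate 3 the TGF-β list (0.076) and the fibroblast list (0.160) were not called, nor was the latter without transgenic replicate 3 (0.069), and Gpx3 lost its call without wild-type replicate 2 or any transgenic replicate, at up to 0.096.

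Of 24 macrophage and myeloid genes, the lysosomal protease Ctss was higher (0.91 ± 0.16, adjusted p 0.036) and none lower; adjusted over the list alone, 7 were higher. The antigen presentation genes H2-Aa (1.10 ± 0.21, adjusted p 0.057), H2-Ab1 (0.90 ± 0.23, 0.161) and Cd74 (0.87 ± 0.23, 0.170) did not pass the threshold over all genes, although each did with array weights (0.012, 0.028 and 0.023), and H2-Aa in 8 of 17 settings, among them the fit without transgenic replicate 1 (0.00998). Camera gave the list a median change of 0.28 and an adjusted p of 2.2e-05, against an adjusted p of 0.54 with an estimated correlation. Of 26 interferon response genes, the class I antigen presentation gene B2m (0.53 ± 0.07, adjusted p 0.011) and the transcription factor Irf7 (0.54, adjusted p 0.045) were higher and none lower, as they were adjusted over the list alone. Camera gave the interferon list a median change of 0.13 and an adjusted p of 0.021, against an adjusted p of 0.57 with an estimated correlation. Of 34 inflammation and cytokine genes, Lcn2 and the cyclooxygenase Ptgs2 (0.82, adjusted p 0.026) were higher, the same 2 adjusted over the list alone, and the list was not called (camera, adjusted p 0.076), except in 6 settings that include the fits without wild-type replicate 1 (0.0314) and transgenic replicate 1 (0.0267). Ctss (without any 1 array other than wild-type replicate 1, up to 0.175), Irf7 (without any 1 of the 6, 0.073 to 0.227), B2m (without wild-type replicate 2 or any transgenic replicate, up to 0.080) and Ptgs2 (without wild-type replicate 3 or any transgenic replicate, up to 0.140) lost their calls. The interferon list lost its call without wild-type replicate 3 (0.140), transgenic replicate 2 (0.079) or transgenic replicate 3 (0.096), and in 7 of 19 settings in all. After quantile normalization the adjusted p was 0.058 for Ctss and 0.099 for Irf7.

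The 30 genes of the unfolded protein response and secretory machinery held no call in limma, neither over all genes nor adjusted over the list alone. A negative change was measured for 25 of them, and 15 had an unadjusted p under 0.05, all lower. Herpud1, which acts in the degradation of misfolded proteins, had a log2 change of −0.58 ± 0.15 (adjusted p 0.16), the ubiquitin ligase Syvn1 of −0.89 ± 0.23 (0.16) and the chaperone Dnajb11 of −0.27 ± 0.08 (0.23). Camera called the list lower, with a median change of −0.19 and an adjusted p of 3.9e-07. With an estimated correlation the adjusted p was 0.57. After median centring limma called Herpud1 (0.041) and Syvn1 (0.027). The mean log2 level of the list was 10.95, 10.81 and 11.06 in wild-type replicates 1, 2 and 3, and 10.77, 10.71 and 10.70 in transgenic replicates 1, 2 and 3. The difference in that level was −0.22 (95% t interval −0.43 to −0.005), and −0.16 (−0.35 to 0.04) without wild-type replicate 3.

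Single enzymes rose in lists that were not called as a whole. The glucuronosyltransferase Ugt2b34 rose by 1.79 ± 0.09 (adjusted p 6.9e-05), from 97.8 ± 9.33 to 376.8 ± 28.3, and was the sole call among 25 androgen and steroid metabolism genes, both over all genes and adjusted over the list alone (camera, adjusted p 0.13, and 0.0475 without wild-type replicate 1). The spermine oxidase Smox rose by 1.12 ± 0.08 (adjusted p 2.9e-04) and was the sole call among 20 polyamine, citrate and zinc genes; adjusted over the list alone, 1 was higher and 1 lower, and camera gave an adjusted p of 0.57. The sterol dehydrogenase Nsdhl rose from 342 ± 13.1 to 808.1 ± 18.6 (adjusted p 1.3e-04) and was the sole call among 22 lipid and cholesterol synthesis genes; adjusted over the list alone, 2 were higher and 1 lower, and camera gave an adjusted p of 0.44. The mean of the lipid list (0.003) and its median (−0.04) differed in sign, and for the polyamine list the median (−8.7e-04) lay opposite to the mean (0.06).

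Of 22 nerve and glia genes, the ubiquitin hydrolase Uchl1 was higher (1.73 ± 0.10, adjusted p 1.1e-04), also adjusted over the list alone (camera, adjusted p 0.19, and 0.0094 without the dimmest probe sets). Of 10 neuroendocrine genes, Pcsk1 was higher and Tph1 lower, also adjusted over the list alone, and the list was not called (camera, adjusted p 0.79). Of 20 endothelial genes, the junction cadherin Cdh5 was higher (0.93 ± 0.12, adjusted p 0.0096), also adjusted over the list alone (camera, adjusted p 0.089, and 0.0369 without wild-type replicate 1). Cdh5 lost its call without wild-type replicate 2, transgenic replicate 2 or transgenic replicate 3, at up to 0.065.

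No member was called in limma in the lists for cell cycle (39 measured, camera adjusted p 0.42), prostate development (33, 0.25), Wnt targets (27, 0.13), urothelium (15, 0.089), skeletal muscle (25, 0.13), smooth muscle (19, 0.74) and adipocytes (17, 0.81). Members with an unadjusted p under 0.05 numbered 4, 4, 2, 1, 3, 1 and 2 in that order. Adjusted over the list alone, the urothelial gene Upk1a (−0.68 ± 0.14, adjusted p 0.083 over all genes, but called in 5 of 17 settings, among them the fit without wild-type replicate 1, 0.0153) was lower, and no other member of these 7 lists passed. Without wild-type replicate 1 camera called the cell cycle (0.0336), urothelial (0.0233) and skeletal muscle (0.0130) lists lower, and without transgenic replicate 1 the urothelial list lower (0.0050) and the smooth muscle list higher (0.0059). With array weights the skeletal muscle list was lower (0.0274). The mitotic checkpoint kinase Bub1b had a log2 change of −0.42 ± 0.10 and an adjusted p of 0.11 (0.035 with median centring and 0.045 with array weights), and the Wnt target Axin2 of 0.25 ± 0.08 and 0.25. Likewise without a call were T and NK cells (20 measured, camera adjusted p 0.57), B and plasma cells (17, 0.96), mast cells (12, 0.74), erythrocytes (4, 0.77), immediate early genes (24, 0.50), histones (9, 0.25), oxidative phosphorylation (29, 0.19) and ribosomal proteins (20, 0.091). Their members with an unadjusted p under 0.05 numbered 0, 2, 2, 0, 2, 1, 3 and 0 in that order. Adjusted over the list alone, the immediate early gene Btg2 (−0.46 ± 0.09, adjusted p 0.066 over all genes, but called in 6 of 17 settings, at down to 0.0145 with array weights) was lower, and no other member of these 8 lists passed. The ribosomal protein list was called higher in 4 settings, among them the fit without wild-type replicate 1 (0.0138). Camera's direction differed in sign from the mean or median change in the T and NK cell, B cell, mast cell and erythrocyte lists.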

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

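Of the tests in this part, the fit with the Svs2, Svs4 and Svs5 level as a covariate was chosen after the data were seen; the others were planned. The 24 largest changes were checked in 405 combinations of gene and setting. Of these, 402 kept direction and call, and the other 3 were Svs3a losing its call without 1 array. The 24 genes were picked on the same arrays for large changes without overlap, so that they held says little about the other calls. In each of 16 refits, all calls shared with the 425 kept their sign, which fits on the same arrays could hardly have failed to give. Without transgenic replicate 3 only 232 of the 425 were still called. Against 425 called probe sets (305 higher, 120 lower), an intensity trend with robust variances gave 678 (224 lower), array weights 1202 (686 higher, 516 lower; 57.1% higher against 71.8%), median centring 578 (314 higher, 264 lower; 54.3% higher), an adjusted p of 0.1 gave 664 (230 lower), 0.01 gave 241 (198 higher, 43 lower), a log2 change of at least 1 gave 175 (136 higher, 39 lower) and treat against a 1.2-fold change 216 (179 higher, 37 lower). Leaving out 1 array gave 234 to 519 called, 193 to 328 higher and 41 to 191 lower, with 519 without wild-type replicate 1, 254 without wild-type replicate 2, 248 without transgenic replicate 2 and 234 without transgenic replicate 3. Stricter thresholds lower counts by construction; the cause of the other shifts was not tested. The number of arrays and the signal of dim genes over background limit these counts.

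No pairing by mouse number was seen: correlations of same-numbered deviations were −0.04, 0.05 and −0.16, and 1 of 3 numbers was its own best partner. With 3 numbers this check cannot exclude a pairing, and pairing in another order was not tested. With the number as a replicate block, 250 probe sets were called (200 higher, 50 lower), 249 of them shared with the 425; Dpp4, Perp, Psca, B2m, Irf7, Ptgs2, Igfbp5, 9530002B09Rik, Gpx3, Cdh5, Ctss, Spink1, Apof and Scgb1b27 lost their calls (adjusted p from 0.055 to 0.210).

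Of the 36 lists 9 were called, 0 with an estimated correlation, and 5 to 16 without 1 array, the lowest without wild-type replicate 3 and the highest without wild-type replicate 1. Lists that changed direction were uncalled in both settings; values are adjusted p. Over 19 settings the call was lost in 10 for the basal list, 7 for interferon, 4 for fibroblasts, 3 for TGF-β, 2 each for extracellular matrix and the unfolded protein response, and 1 each for the progenitor, Akt and myeloid lists. Of the uncalled lists, calls were gained in 6 settings for inflammation, 4 for ribosomal proteins, 2 each for the steroid metabolism, seminal vesicle, urothelial, skeletal muscle and endothelial lists, and 1 each for the secretory, luminal, cell cycle, smooth muscle, nerve and glia, neuroendocrine and oxidative phosphorylation lists. The gains of the luminal (0.022), neuroendocrine (0.0099) and oxidative phosphorylation (0.0099) lists came from fry and not from camera. The B cell list changed direction with quantile normalization (0.921), without dim probe sets (0.880), with array weights (0.971), the replicate block (0.947), the Svs covariate (0.889) and fry (0.871). Without dim probe sets the vas deferens and mast cell lists did (0.343 each), with array weights smooth muscle (0.360) and adipocytes (0.939), with fry the secretory (0.479) and lipid (0.363) lists, and on ranks the neuroendocrine list (0.991). Without 1 array, directions turned at least once in the polyamine (0.212 to 0.735), smooth muscle (0.0059 to 0.800) and adipocyte (0.605 to 0.906) lists. They also turned in the T and NK (0.249 to 0.957), B cell (0.563 to 0.923) and mast cell (0.563 to 0.911) lists. The neuroendocrine (0.634 to 0.941) and immediate early (0.160 to 0.695) lists turned as well. These ranges cover every fit without 1 array, whether the direction turned or not. The smooth muscle value of 0.0059, without transgenic replicate 1, kept its direction (higher). Where directions turned, adjusted p ran from 0.560 (smooth muscle, without transgenic replicate 2) to 0.957 (T and NK, without wild-type replicate 3). Svs2, uncalled throughout, moved from −0.35 to 1.13 with array weights and lay between −1.42 and 1.49 without 1 array. With an added constant of 1, Perp, Irf7, Ptgs2, Ccnd2, Igfbp5, Ctss and 9530002B09Rik lost their calls (adjusted p from 0.061 to 0.090). The cause was not tested.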

Other observations

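Every test in this part was chosen after the results were seen, apart from the limma and camera calls it starts from, and the genes named here beyond the fixed rule were chosen after their values were seen. Of 22 measured kallikrein (Klk) genes, 8 were called, all of the Klk1b group and all higher in transgenic prostates, and 14 did not pass the threshold, against 0.358 called genes by chance (hypergeometric test, adjusted p 7.2e-07 over 619 gene families). That test counts genes as independent, and signal shared among the near-identical kallikrein genes was not separated. Its p-value can therefore not be taken as the strength of a family-wide change. Beyond Klk1b24, Klk1b27 and Klk1b7-ps the called kallikrein genes were Klk1b22 (2.38), Klk1b11 (2.22), Klk1b1 (1.76), Klk1b5 (1.38) and Klk1b8 (1.05). Each had a wild-type mean below 66.9, the lowest 95th percentile of olfactory receptor probe sets. For Klk1b1 (58.5) and Klk1b8 (52.6) the transgenic mean also lay below it. Over all settings the log2 changes ran from 1.46 to 3.09, 1.40 to 2.81, 0.81 to 3.12, 0.88 to 1.70 and 0.52 to 1.56 in that order of genes. The count of 8 higher Klk genes was the same under quantile normalization and median centring; 3 of the 7 left were called without dim probe sets, and array weights added 1 lower Klk gene. Of 11 measured secretoglobin genes, 3 were called and lower, also under quantile normalization and median centring, but the family as a whole did not pass (adjusted p 0.13): Scgb2b27 (−5.55), Scgb2b24 (−1.12) and Scgb1b27 (−1.04). Without transgenic replicate 2, 1 of the 11 was called. Scgb2b24 was not called without transgenic replicate 2 (0.056), nor Scgb1b27 without wild-type replicate 2 or any transgenic replicate (up to 0.110), nor with the mouse number as a replicate block (0.055).

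Several other neighbours on the chromosome changed together. The acetylcholinesterase gene Ache (2.72 ± 0.10, adjusted p 7.6e-06) rose from 33.2 ± 1.06 to 310.3 ± 36.2 (SD, n = 3 each), and the adjoining Ufsp1 rose by 1.90. The murinoglobulin gene Mug2 rose by 2.46 beside Mug1, and Aldh1a7 by 0.89 beside Aldh1a1. The epithelial calcium channel genes Trpv6 and Trpv5 fell, with log2 changes of −1.18 and −0.90, as did Sbpl (−1.22), the neighbour of Sbp. The wild-type means of Ache and Mug2 and the transgenic mean of Trpv5 lay below 66.9.

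Neighbouring genes that were called in the same direction numbered 23 pairs, against a mean of 3.15 and a maximum of 13 in 10000 permutations of the calls over 19919 placed genes (p 0.0001, the smallest these permutations can give). There were 0 neighbouring pairs of opposite direction, against a mean of 2.12. Probe sequences shared by related genes are a technical explanation: 14 of the 23 pairs have like-named members, such as the kallikreins, and for these shared probes and shared regulation cannot be told apart, because probe sequences were not used. The 9 pairs with unlike names, such as Ache and Ufsp1, exceeded the permuted mean of 2.67 (permutation p 0.0014). The test was set up to count such an excess against shared sequence, but that bound was wrong. Overlapping transcripts or shared sequence would give an excess too, so the same holds for the 9 pairs. No other cause of joint calls was tested for any of the 23 pairs.

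The large rises of secretory genes could come from what was dissected. Seminal vesicle tissue was tested first, since Svs2, Svs4 and Svs5 varied between mice. With their level as a covariate, 12 of the 12 largest rises and 12 of the 12 largest falls stayed past the threshold. The median rise moved from 4.05 to 3.99. That level differed by only 0.93 between the genotypes, and the genes were picked for non-overlap. The covariate fit could therefore hardly have removed them, and the levels by mouse say more. Wild-type replicate 1, with a mean Svs level of 10.05, had a median of 5.64 over the 12 risen genes. The other wild-type mice had medians of 5.53 and 5.61, and the transgenic mice of 9.58 to 9.90. Transgenic replicate 2, with a mean Svs level of 5.53, had a median of 9.58. These values argue against tissue rich in Svs2, Svs4 and Svs5 as the cause. Vas deferens or epididymis tissue was not tested. A different share of prostate lobes stays open: the anterior lobe gene Tgm4 had a log2 change of 0.0676, but it lies near the top of the intensity range and no profile of single lobes was used here. The genotype itself is the biological explanation the design gives, and it was not tested apart from the lobes.

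The lower endoplasmic reticulum folding genes were weighed against handling stress in 1 mouse, since wild-type replicate 3 had the highest level. The mean log2 level of the immediate early list was also highest there, at 8.10. It was 7.68 and 7.90 in wild-type replicates 1 and 2, and 7.87 to 7.93 in transgenic mice. Wild-type replicate 3 also had the highest median intensity (110.8), so that level cannot decide for stress. Without that array the list's median change was −0.136 (bootstrap interval −0.191 to −0.096 over genes, camera adjusted p 3.7e-06) against −0.192 with it. These values do not measure the spread between mice: compared by mouse, the mean level of the list differed by −0.16 without that array (t interval −0.35 to 0.04), so that mouse as the cause cannot be told apart from genotype with 2 wild-type mice left. Without 1 array the list's adjusted p ranged from 9.9e-12 to 0.0013, and over all settings it reached 0.57. A lower share of luminal epithelium would lower luminal markers by about as much. Their median change was 0.0394 (bootstrap interval over genes −0.038 to 0.143). By mouse the mean level of the luminal markers moved 0.31 above that of the folding list (t interval 0.07 to 0.55). These values argue against a lower share of the cells that carry these markers as a set. A shift among kinds of luminal cells was not tested. Genotype stays open as a hypothesis, and the call was lost with an estimated correlation and with fry.

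The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 425 probe sets and the highest of the others 0, so 1 of 10 splits called as many. The real split called 9 lists and the highest of the others 10, and 4 of the 10 splits called at least 9.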
